A study of Streptomyces natalensis with 4 samples.

How the data were processed

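Total RNA of 4 cultures of Streptomyces natalensis HW-2 was depleted of ribosomal RNA, made into strand-marking libraries and sequenced on an Illumina instrument, per the labels. The deposited table lists 7477 genes, each with its contig, start and end, a description and a count and an FPKM value per library. For the libraries of 40 h the deposited values are counts of reads or fragments per gene, per the file headers, and all are whole numbers. For the libraries of 80 h the deposited values are expected counts, in which 41 genes of the control and 51 of the elicitor library carry a fraction, as tools give that share reads among repeated genes. The authors also give FPKM values, per kilobase of gene and scaled by a library total. FPKM has 9 decimals at 40 h and 2 decimals at 80 h. Reads were aligned with Bowtie2 per the submitters' processing notes; its version, the counting tool, the annotation version and any pooling of cultures are not given in the sources used here. No reads, genome sequence or natamycin titre were used here.

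Gene ratios were computed from the counts, with expected counts rounded to whole numbers throughout. Genes with at least 10 counts in at least 1 library were kept, 7426 in all. Libraries were scaled by TMM in edgeR 4.0.16 (R 4.3.3), with factors of 1.32 (control, 40 h), 1.33 (elicitor, 40 h), 0.626 (control, 80 h) and 0.911 (elicitor, 80 h). The log2 ratio of 2 libraries was taken after adding a prior count of 0.5, scaled to library size. Its 95% interval is an exact binomial (Clopper-Pearson) interval of the counts given their sum. Folds are ratios of scaled counts without the prior count. A gene was called at least 2-fold apart where the ratio was 2-fold or more and the interval excluded a ratio of 1. Where 1 library had 0 counts, the fold is a bound against a floor of 3 counts in that library, which is a level (CPM) of 0.164, 0.103, 0.728 and 0.476 in the order given for the factors. The 13 genes of the control and 9 of the elicitor library at 0 counts at 40 h compare with 826 and 518 at 80 h, and the median kept gene had 277, 485, 46 and 81 counts in the same order.

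Comparisons were elicitor against control at 40 h and at 80 h, and 80 h against 40 h without and with elicitor. With 1 library per group, none of the 4 comparisons has a test of the condition. An additive fit of harvest time and elicitor over all 4 libraries leaves 1 residual degree of freedom. Harvest time is fitted, and the change of the elicitor ratio between 40 h and 80 h is taken as noise. A response that differs between the times therefore counts as noise there. The fit was added after seeing the data, with edgeR's quasi-likelihood test. Gene lists, the rule for named genes, the calls and most alternatives were fixed before the data were examined. Of 43 gene lists matched on descriptions, 1 found no gene and 1 found only enzymes that act on ribosomal RNA, and 41 were used. The list of ribosomal RNA enzymes (4 genes) was left out after its values were seen; it had lain above random lists with elicitor at 80 h and below them over time without elicitor. Each list's median log2 ratio was set against 10000 random lists of equal size matched on level in 10 bins, and its range over counting error came from 200 simulated recounts. Named are, per comparison, the 8 genes with the largest ratio in each direction among called genes with at least 100 counts in the higher library and an informative description. Also named are up to 4 members (here 3 in the elicitor comparisons and 2 in the time comparisons) with the largest ratio of each list described, some of the 5 highest genes of each library, and the genes of the polyene cluster list by value or as a group. The ranking uses the log2 ratio with the prior count, on which it depends for genes at 0 counts. Other genes were chosen after their values were seen, as stated where they appear.

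Alternatives were scaling by total counts of kept genes, by the median of ratios and by total counts without the 10 highest genes, no filter and a filter of 100 counts, a prior count of 5, the authors' FPKM with a pseudocount of 1, and thresholds of 1.5-fold and 4-fold. Added after seeing the data were genes of at least 600 bp only, TMM within 1 harvest time, matching of descriptions with letter case kept, a narrower span of the polyene cluster, and the calls at both times under each scaling. Also added were shifts of each list along the gene order (7425 shifts), which keep neighbouring genes together, with each ratio taken less the median of its level bin. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

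The procedure was tested on simulated data with the depths of these libraries. In the 40 h comparison 98% of genes made 3-fold different and 100% of those made 8-fold different were called in the right direction, and at 80 h 83.9% and 93.5%. The time comparisons recovered 95% and 98% without and 92% and 99% with elicitor. Of the simulated genes without a difference 0.305% to 0.787% were called, and 95.5% to 96.5% of intervals held the simulated ratio. The simulated counts varied by counting error alone, which is what the intervals assume. They held no variation between cultures and no broad shift between libraries, so these rates do not cover errors from those sources.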

Results

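RNA was sequenced from cultures of Streptomyces natalensis strain HW-2, a filamentous soil bacterium of a species that makes the antifungal polyene natamycin. The fungal elicitor, per the labels a small compound purified from the culture broth of the mould Penicillium chrysogenum, was added to cultures at 24 h. Cultures with and without elicitor were harvested at 40 h and at 80 h, and each of the 4 groups has 1 library, so no comparison has a replicate check. The control library of 40 h held 13862063 counts, the elicitor library of 40 h 21951716, the control library of 80 h 6588767 and the elicitor library of 80 h 6918388. The file lists 7477 genes on 59 contigs of a draft genome. Intervals given with ratios are 95% intervals for counting error only, and with 1 library per group they hold no variation between cultures. The reads were amplified by PCR and carry no molecular identifiers, so the intervals can be too narrow for counting error as well.

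At 40 h the gene with the most counts was the catalase SNA_RS32920, which takes apart hydrogen peroxide. It held 2.51% of the counts of the control library (Wilson 95% interval 2.501 to 2.518) and 2.61% of those of the elicitor library (2.60 to 2.62). At 80 h the proteasome ATPase SNA_RS11520, part of the machine that breaks down tagged proteins, held 2.38% of the control library (2.37 to 2.39) and 1.10% of the elicitor library (1.09 to 1.10). The Pup ligase SNA_RS11480, which attaches that tag, was also among the 5 highest of the control library of 80 h, with 1.16% (1.15 to 1.16). The other genes among the 5 highest of the 40 h libraries included the thiamine gene ThiC SNA_RS02040 and glyceraldehyde-3-phosphate dehydrogenase SNA_RS10305 in the control, and a Crp/Fnr-type regulator SNA_RS28870, a cysteine desulfurase SNA_RS28865 and the polyketide synthase SNA_RS21330 in the elicitor library. In the elicitor library of 80 h the hypothetical protein SNA_RS15740 (1.28%), NADH dehydrogenase SNA_RS04150 (1.07%) and ribosomal protein S1 SNA_RS09705 (0.948%) were among the 5 highest.

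The first comparison asked how the elicitor library differed from the control library at 40 h. Potassium uptake genes made up 4 of the 8 named genes with the largest ratios that were higher with elicitor. The genes for subunits A (SNA_RS30095, contig 56, 56558 to 58234) and C (SNA_RS30085, 53734 to 54396) of a potassium-transporting ATPase, a high-affinity pump that bacteria use when potassium is scarce, were 91.5-fold (84.1 to 99.8) and 82.9-fold (71.4 to 96.8) higher. SNA_RS30090 (54417 to 56525), which lies between them and is listed as potassium transporter KtrB, was 119-fold (108 to 132) higher, and a further gene listed as KtrB, SNA_RS22360 (contig 29, 643540 to 645642), was 89.6-fold (71.2 to 114) higher. Sugar uptake genes next to each other on contig 25 were also higher: the substrate-binding protein SNA_RS15425 (67612 to 68943) by 132-fold (106 to 167), the mannitol permease SNA_RS15415 by 93.8-fold (67.03 to 136) and the sugar permease SNA_RS15420 by 84.7-fold (65.2 to 112). The short-chain dehydrogenase SNA_RS18640 (contig 27, 48173 to 48982) was 106-fold (87.9 to 129) higher.

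Genes for the breakdown of ketoacids and phenylacetate made up 4 of the 8 named genes with the largest ratios that were lower with elicitor at 40 h. On contig 3, the alpha-ketoacid dehydrogenase beta subunit SNA_RS02620 (360559 to 361593) was 62.95-fold (50.3 to 79.9) lower. Its neighbours SNA_RS02615, listed as the pyruvate dehydrogenase E1 alpha subunit, and SNA_RS02625, the E2 subunit of branched-chain ketoacid dehydrogenase, were 55.9-fold (47.1 to 66.9) and 29.9-fold (25.7 to 35.01) lower. PaaN SNA_RS02595, of the pathway that degrades phenylacetate, was 47.6-fold (44.4 to 51.2) lower. On contig 34 the glutamine amidotransferase SNA_RS25180 and the AraC-type regulator SNA_RS25185 beside it were 53.1-fold (43.1 to 66.2) and 42.8-fold (34.5 to 53.9) lower. On contig 29 the cytochrome P450 SNA_RS22945 was 37.5-fold (33.99 to 41.5) lower, and SNA_RS22950, a member of the PvcA family that makes isonitrile groups, was 31.8-fold (26.3 to 38.8) lower.

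**Figure D1:**
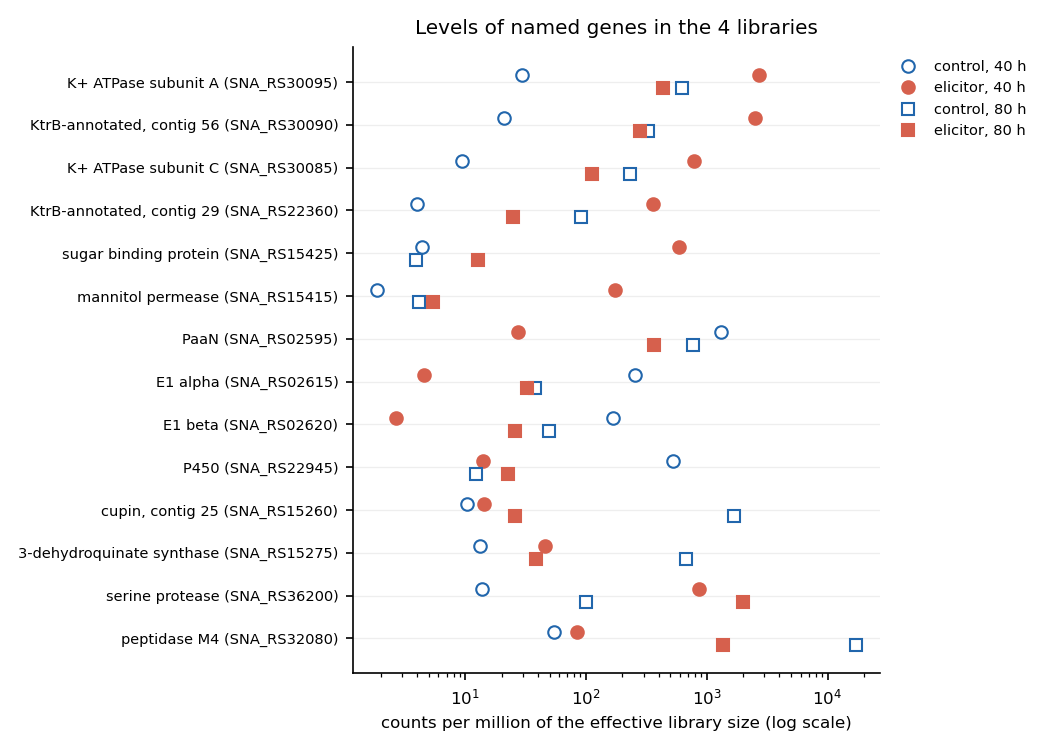
Levels of 14 named genes in each of the 4 libraries, as counts scaled to the effective library size (CPM) on a log axis; circles stand for 40 h, squares for 80 h, open symbols for control and filled symbols for elicitor, 1 library each. The potassium gene SNA_RS30090 was 119-fold higher and PaaN SNA_RS02595 was 47.6-fold lower in the elicitor library at 40 h.

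In all, 729 of 7426 genes were at least 2-fold higher and 464 at least 2-fold lower in the elicitor library at 40 h. A further 26 genes differed 2-fold with an interval that held a ratio of 1. With the authors' FPKM values in place of scaled counts, and no interval, the split was 868 higher and 249 lower. Of the 41 gene lists, 5 had a median above and 9 a median below the middle 95% of random lists of genes matched on level. Random lists are scattered, while members of some lists are neighbours; against shifts of each list along the gene order, an alternative added after seeing the data, 2 lay above and 9 below. The lists of the polyene cluster, polyketide synthases and nitrogen assimilation then lay inside. Polyketide synthases also lay inside with a prior count of 5, and development and oxidative stress with genes of at least 600 bp only.

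Arginine synthesis was the list with the lowest median at 40 h: of its 11 genes 0 were higher, 7 lower and 4 not called, with a median log2 ratio of -1.07. Acetylglutamate kinase SNA_RS12540, an early step of the pathway, was 3.33-fold (3.07 to 3.61) lower, the ornithine acetyltransferase SNA_RS12535 3.02-fold (2.88 to 3.17) and ornithine carbamoyltransferase SNA_RS29770 2.66-fold (2.49 to 2.84). Lists of central carbon metabolism also had negative medians. In the list of the tricarboxylic acid (TCA) cycle (21 genes, median -0.80) 2 were higher, 3 lower and 16 not called. Aconitate hydratase SNA_RS29445 was 2.48-fold (2.44 to 2.53) lower, and the succinate dehydrogenase or fumarate reductase subunits SNA_RS33475 and SNA_RS33480 were 3.15-fold (3.004 to 3.31) and 2.72-fold (2.51 to 2.96) higher. Pentose phosphate genes (10 genes, median -0.72) had 0 higher, 1 lower and 9 not called, the lower one being 6-phosphogluconate dehydrogenase SNA_RS02355 at 2.46-fold (2.39 to 2.54). Among 18 glycolysis genes (median -0.40) 1 was higher, 2 lower and 15 not called. Pyruvate kinase SNA_RS32155 was 3.39-fold (3.30 to 3.49) lower, glucose-6-phosphate isomerase SNA_RS10330 2.29-fold (2.23 to 2.35) lower and a fructose-bisphosphate aldolase, SNA_RS15280, 4.52-fold (3.75 to 5.50) higher.

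Lists for protein upkeep and synthesis had negative medians as well. The chaperone and protease list (23 genes, median -0.69) had 3 higher, 6 lower and 14 not called. The Clp protease subunit SNA_RS16770 was 4.19-fold (3.26 to 5.46) higher and the GrpE-type exchange factor SNA_RS22750 3.17-fold (1.99 to 5.26) higher, while a lower member was a copper chaperone, SNA_RS01850, which carries a metal and does not fold proteins, at 3.08-fold (2.97 to 3.21). The 36 translation factors and tRNA ligases had a median of -0.32 with 0 higher, 1 lower and 35 not called, the lower one being lysine-tRNA ligase SNA_RS36595 at 2.24-fold (2.17 to 2.32). Oxidative stress genes (36, median -0.41) had 0 higher, 5 lower and 31 not called. The organic hydroperoxide reductase of the Ohr family SNA_RS17690 was 3.94-fold (3.71 to 4.19) lower and an alkyl hydroperoxide reductase SNA_RS33695 2.42-fold (2.21 to 2.66) lower. That list also took in SNA_RS34230, a deoxyribose-phosphate aldolase of nucleoside breakdown, through its name. Without such members, an alternative chosen after seeing the data, the median of 31 genes was -0.42, and over the list's 20 genes of at least 600 bp it was -0.26.

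Aromatic amino acid and histidine synthesis (37 genes, median -0.34) had 2 higher, 4 lower and 31 not called. Indole-3-glycerol-phosphate synthase SNA_RS13755, of tryptophan synthesis, was 3.01-fold (2.65 to 3.43) lower, while 3-dehydroquinate synthase SNA_RS15275 was 3.49-fold (3.04 to 4.02) higher and aminodeoxychorismate lyase SNA_RS01905, of folate synthesis, 3.58-fold (3.04 to 4.24) higher. SNA_RS15275 lies on contig 25 beside SNA_RS15280, the higher gene of the glycolysis list, so these 2 are neighbours and not separate exceptions. Among 111 genes taken as TetR-type regulators (median -0.19) there were 3 higher, 11 lower and 97 not called, with SNA_RS05050 at 10.2-fold (8.29 to 12.5) and SNA_RS30615 at 6.39-fold (4.97 to 8.32) lower. The list also took in SNA_RS25990, a lysine synthesis enzyme (tetrahydrodipicolinate synthase), and without such members, also chosen after seeing the data, the median of 94 genes was -0.23.

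Lists with a median above the middle 95% of random lists at 40 h included development, nitrogen assimilation, secreted hydrolases and polyketide synthases. Of these, nitrogen assimilation and polyketide synthases lay inside when set against shifts along the gene order. Of 16 development genes (median 0.52) 5 were higher, 0 lower and 11 not called. The SsgA-type sporulation protein SNA_RS05365 was 7.90-fold (7.05 to 8.89) higher, and the chaplins SNA_RS10925 and SNA_RS11895, which coat aerial hyphae, 4.69-fold (4.35 to 5.07) and 3.59-fold (3.32 to 3.88). With genes of at least 600 bp only, an alternative added after seeing the data, 3 development genes were left and their median was -0.10. Nitrogen assimilation (26 genes, median 0.37) had 6 higher, 4 lower and 16 not called. The nitrite reductase subunits SNA_RS07170 and SNA_RS07165 were 3.95-fold (3.24 to 4.85) and 3.32-fold (2.13 to 5.37) higher, and the glutamine synthetase gene SNA_RS11360 was 5.43-fold (4.70 to 6.30) lower. Among 56 secreted hydrolase genes (median 0.29) 8 were higher, 1 lower and 47 not called. Phospholipase C SNA_RS36720 was 4.63-fold (4.50 to 4.77) higher, a glycosyl hydrolase SNA_RS14050 3.45-fold (3.01 to 3.96) higher and a lipase SNA_RS19100 3.31-fold (2.97 to 3.69) lower. The polyketide synthase list (18 genes, median 0.37) had 2 higher, 0 lower and 16 not called. It shares the synthases of the polyene cluster with the cluster list, so these lists are not independent. With genes of at least 600 bp only, 8 members were left and their median was 0.64. The type I synthase SNA_RS21055, outside the polyene cluster, was 2.29-fold (2.22 to 2.36) higher. The other higher member, SNA_RS23495 at 2.44-fold (1.67 to 3.65), is a polyketide cyclase and not a synthase.

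**Figure D2:**
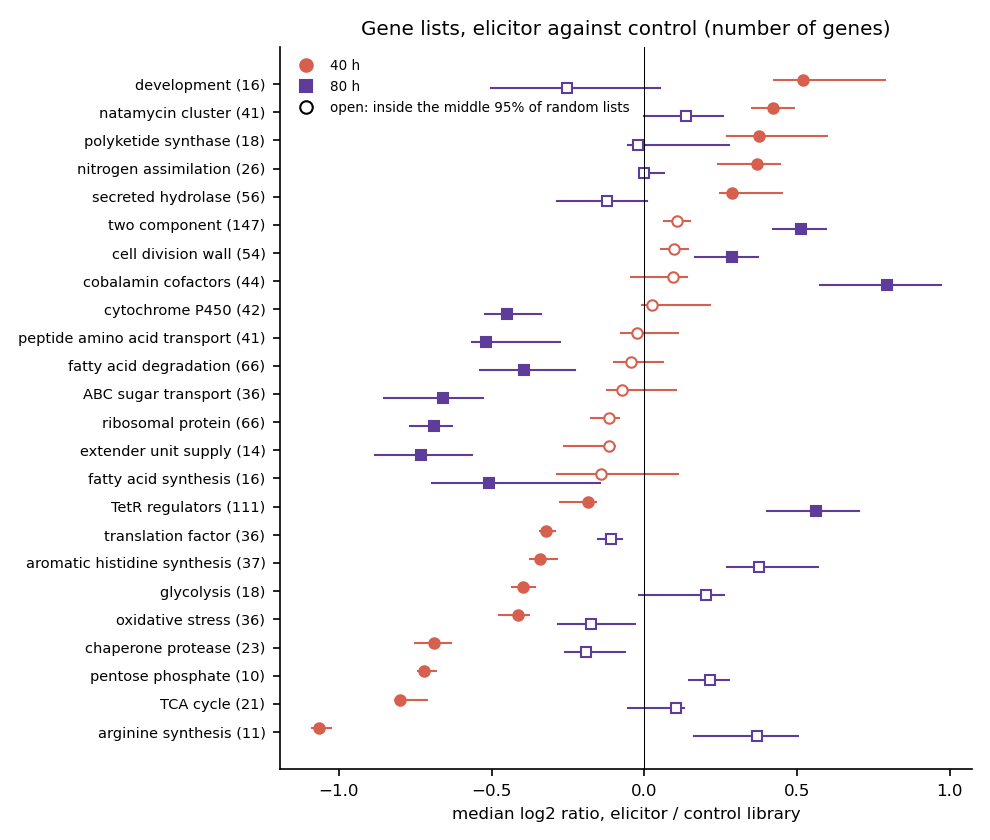
Median log2 ratio of elicitor over control for the gene lists that lay outside the middle 95% of random lists at 40 h or 80 h; filled symbols lay outside, open symbols inside, lines are the 95% range over simulated recounts, and 1 library stands behind each side of a ratio. Arginine synthesis had the lowest median at 40 h (-1.07), and at 80 h the medians of fatty acid degradation (-0.39), peptide and amino acid transport (-0.52) and cytochrome P450 (-0.45) change sign when libraries are scaled by total counts. At 40 h the lists of the polyene cluster, polyketide synthases and nitrogen assimilation lay inside when set against shifts along the gene order.

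The polyene-type gene cluster on contig 29 was taken as the natamycin cluster from its gene content alone, since the file gives no gene symbols for it. It holds type I polyketide synthases, a cholesterol oxidase, cytochrome P450 genes and amino sugar genes. The fixed list takes 20 genes on either side of the cholesterol oxidase SNA_RS21355, from 328766 to 441518, 41 genes in all. With TMM scaling, the list's median log2 ratio of elicitor over control at 40 h was 0.42 with 5 higher, 2 lower and 34 not called. That median lay above the middle 95% of random lists but inside when set against shifts along the gene order. At 80 h the list's median was 0.14 with 6 higher, 2 lower and 33 not called, inside the middle 95% of random lists. Over the narrower span from SNA_RS21305 to SNA_RS21410 (340175 to 431238, 23 genes), chosen after seeing the data, the medians were 0.68 and 0.08. Scaling by total counts would add 0.54 to the log2 ratios at 80 h and 0.009 at 40 h. For the list of 41 genes, that the median was lower at 80 h therefore depends on the scaling. For the narrower span such a shift would shrink the gap between the times but leave the median lower at 80 h. These 23 genes held 2.99% of the control library and 4.56% of the elicitor library at 40 h, and 2.17% and 3.41% at 80 h. These shares are of total counts, without TMM scaling.

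Most synthesis genes of this cluster were higher with elicitor at 40 h by less than 2-fold. The log2 ratio was 0.63 (0.61 to 0.65) for the polyketide synthase SNA_RS21320, 0.76 (0.74 to 0.78) for SNA_RS21325, 0.59 (0.58 to 0.61) for SNA_RS21330, 0.70 (0.67 to 0.72) for SNA_RS21375 and 0.18 (0.17 to 0.19) for SNA_RS21385. The cholesterol oxidase SNA_RS21355 had 0.81 (0.79 to 0.83), and the cytochrome P450 genes SNA_RS21365 and SNA_RS21390 0.61 (0.59 to 0.63) and 0.35 (0.32 to 0.38). The regulator genes at the edge of the cluster differed in direction: the LuxR-type regulator SNA_RS21305 had 1.66 (1.63 to 1.68) and the transcriptional regulator SNA_RS21310 -1.84 (-1.93 to -1.74). With libraries scaled by TMM these were at 80 h -0.34 (-0.39 to -0.29) and 1.17 (1.05 to 1.28). The synthases SNA_RS21330, SNA_RS21375 and SNA_RS21385 had 0.97 (0.94 to 1.01), 1.02 (0.94 to 1.10) and 0.85 (0.82 to 0.88) at 80 h, whereas SNA_RS21320 had -0.02 (-0.05 to 0.01). The synthases SNA_RS21320, SNA_RS21325 and SNA_RS21330 had fractional counts at 80 h, as genes with shared reads do, so their values there are uncertain. Scaling by total counts would add 0.54 to each of these ratios at 80 h, which turns SNA_RS21305 to 0.20 and SNA_RS21320 to 0.52. The decarboxylase SNA_RS21400 and the iron transporter SNA_RS21405 at the far end were lower at 80 h, with -1.22 (-1.45 to -0.998) and -1.77 (-1.93 to -1.62).

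**Figure D3:**
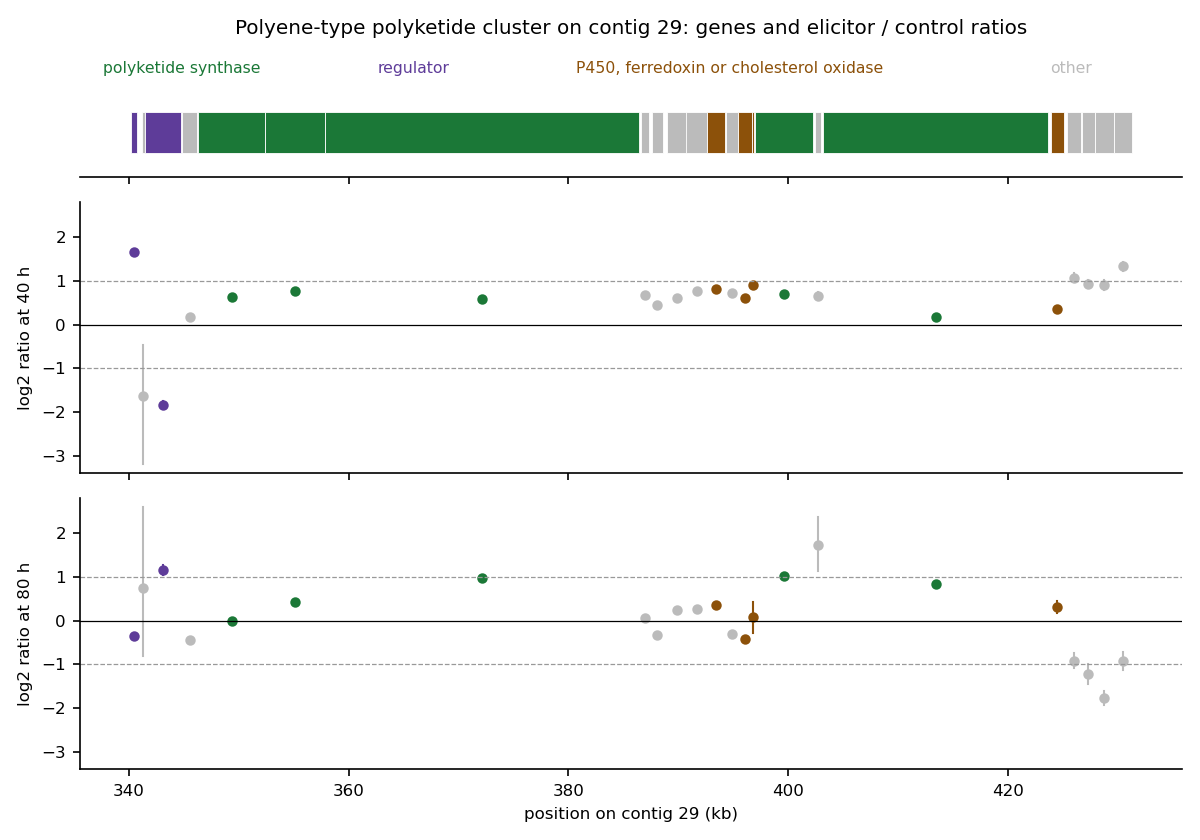
Map of the 23 genes of the polyene-type cluster on contig 29 (position in kb) with the log2 ratio of elicitor over control at 40 h and at 80 h; points are single genes, vertical lines their 95% counting intervals and dashed lines a 2-fold difference. With TMM scaling the median was 0.68 at 40 h and 0.08 at 80 h, and the regulator SNA_RS21310 was lower with elicitor at 40 h (-1.84) and higher at 80 h (1.17). Scaling by total counts would add 0.54 to the ratios at 80 h.

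The same question was asked at 80 h. A 2-component signalling pair and the serine protease next to it on contig 62 were higher in the elicitor library: the protease SNA_RS36200 (227411 to 228469) by 19.7-fold (17.9 to 21.8), the sensor kinase SNA_RS36190 (225138 to 226568) by 14.5-fold (11.4 to 18.8) and the response regulator SNA_RS36195 (226565 to 227302) by 11.6-fold (9.72 to 14.1). On contig 29 the cyclase SNA_RS22220 was 11.6-fold (6.34 to 23.6) higher. The GntR-type regulator SNA_RS04710 was 9.001-fold (4.41 to 21.4) higher, the membrane protein SNA_RS14865 8.48-fold (7.01 to 10.3), carbonic anhydrase SNA_RS23095, which interconverts carbon dioxide and bicarbonate, 7.46-fold (4.40 to 13.6), and the DNA repair gene RecO SNA_RS06985 7.36-fold (5.12 to 10.9).

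Genes between 29419 and 44353 on contig 25 made up 6 of the 8 named genes with the largest ratios among those lower with elicitor at 80 h. The cupin SNA_RS15260 (32061 to 32585) was 64.4-fold (55.2 to 75.7) lower, the oxidoreductase SNA_RS15250 22.7-fold (19.8 to 26.1), the transporter SNA_RS15255 21.8-fold (18.7 to 25.7), 3-dehydroquinate synthase SNA_RS15275 17.5-fold (15.4 to 20.1), a further cupin SNA_RS15300 15.8-fold (15.1 to 16.7) and a salicylate monooxygenase SNA_RS15285 12.8-fold (9.25 to 18.2). Outside that stretch, the protease SNA_RS05385 (contig 8, 118448 to 120817) was 17.3-fold (16.1 to 18.6) lower and the AraC-type regulator SNA_RS25540 17.5-fold (8.86 to 39.3).

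At 80 h, 956 genes were at least 2-fold higher and 697 at least 2-fold lower in the elicitor library, and 834 more differed 2-fold with an interval that held 1. Of the lower genes 15 had 0 counts in the elicitor library, and of the higher genes 55 had 0 counts in the control library. The split depended on the scaling: it was 1996 higher and 272 lower with libraries scaled by total counts, which moves the median of all genes by 0.54 and the list medians by about as much, 1964 and 277 with total counts without the 10 highest genes (a move of 0.52), 780 and 913 with the median of ratios, and 1839 and 293 with the authors' FPKM. Of the 41 lists, 4 lay above and 7 below the middle 95% of random lists, and 4 and 8 against shifts along the gene order, with osmoprotection added. Fatty acid synthesis lay inside with total counts and with a filter of 100 counts, cell division and cell wall with that filter, and ribosomal proteins over genes of at least 600 bp. Of lists inside here, the respiratory chain lay below with that filter and with that length, osmoprotection below with that length, and terpene synthesis and aromatic and histidine synthesis above with that filter.

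With TMM scaling, lists for polyketide extender units and for sugar and peptide uptake had negative medians with elicitor at 80 h. Of 14 genes for polyketide extender units (median -0.73, and -0.19 with total counts) 0 were higher, 5 lower and 9 not called. Crotonyl-CoA reductase SNA_RS27220, which makes precursors of such units, was 8.31-fold (8.01 to 8.63) lower, methylmalonyl-CoA epimerase SNA_RS32255 3.54-fold (3.38 to 3.71) and methylmalonyl-CoA mutase SNA_RS25490 2.44-fold (2.27 to 2.62). Sugar transport and utilisation (36 genes, median -0.66, and -0.12 with total counts) had 3 higher, 11 lower and 22 not called. The binding proteins SNA_RS27675 and SNA_RS27670 were 9.86-fold (8.37 to 11.7) and 4.04-fold (3.53 to 4.63) lower. Its other lower member named here, xylose isomerase SNA_RS20580 at 5.83-fold (5.38 to 6.31), is an enzyme and not a transporter. Peptide and amino acid transport (41 genes, median -0.52, and 0.01 with total counts) had 3 higher, 5 lower and 33 not called. The branched-chain amino acid binding protein SNA_RS09660 was 3.36-fold (3.18 to 3.54) lower and the permease SNA_RS11095 3.31-fold (2.95 to 3.70) lower, while the permease SNA_RS30570 was 2.68-fold (1.81 to 4.08) higher.

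Fatty acid degradation (66 genes) had a median of -0.39, of -0.34 with genes at 0 counts set to their bound and of 0.01 with total counts, with 4 higher, 18 lower and 44 not called. The acyl-CoA dehydrogenases SNA_RS25320 and SNA_RS05940 were 5.07-fold (4.58 to 5.61) and 4.60-fold (4.13 to 5.13) lower and acetyl-CoA acetyltransferase SNA_RS07925 4.17-fold (3.92 to 4.42). Among 16 fatty acid synthesis genes (median -0.51, at the bound -0.47, but -0.01 with total counts without the 10 highest genes) 1 was higher, 3 lower and 12 not called. The ketoacyl reductase SNA_RS08135 was 3.79-fold (3.13 to 4.62) lower, the acyl carrier protein SNA_RS07595 2.18-fold (2.03 to 2.35) lower and the malonyltransferase SNA_RS07605 2.65-fold (2.20 to 3.22) higher. Cytochrome P450 genes (42, median -0.45, but 0.09 with total counts and 0.07 without the 10 highest genes) had 2 higher, 10 lower and 30 not called. SNA_RS07920 and SNA_RS06955 were 6.66-fold (4.28 to 10.7) and 4.12-fold (3.95 to 4.30) lower and SNA_RS16480 6.97-fold (4.02 to 13.1) higher. Ribosomal protein genes (66, median -0.69, at the bound -0.68, and -0.15 with total counts) had 3 higher, 15 lower and 48 not called. L23 SNA_RS37325 and S19 SNA_RS37335 were 3.15-fold (2.46 to 4.04) and 3.12-fold (2.35 to 4.16) lower, and S16 SNA_RS31265 was 5.37-fold (4.93 to 5.86) higher.

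Lists of regulators, cofactor genes and cell wall genes had positive medians with elicitor at 80 h. The list of 2-component systems (147 genes, median 0.51, at the bound 0.50) had 33 higher, 3 lower and 111 not called. Besides the pair on contig 62, the response regulator SNA_RS18095 was 4.41-fold (2.91 to 6.93) higher. Of 111 genes taken as TetR-type regulators (median 0.56, at the bound 0.39) 25 were higher, 5 lower and 81 not called, among them SNA_RS16530 at 5.56-fold (4.01 to 7.88) and SNA_RS32455 at 4.55-fold (3.35 to 6.32). Without the tetrahydro-compound enzymes the median of 94 genes was 0.67. The cofactor synthesis list (44 genes, median 0.80, at the bound 0.53) had 9 higher, 1 lower and 34 not called. Genes listed as CobW, SNA_RS19660 and SNA_RS30275, were 4.34-fold (3.03 to 6.38) and 3.08-fold (2.15 to 4.52) higher and thiamine phosphate synthase SNA_RS09135 3.36-fold (2.82 to 4.02). Cell division and cell wall genes (54, median 0.29, at the bound 0.18) had 12 higher, 1 lower and 41 not called. The penicillin-binding protein SNA_RS06560, of the family that cross-links the wall, was 5.55-fold (4.58 to 6.78) higher, the rod shape protein SNA_RS06130 4.59-fold (3.91 to 5.43) and the diaminopimelate ligase of wall precursor synthesis SNA_RS09225 4.40-fold (3.49 to 5.61).

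Across the 7426 genes the elicitor ratio at 40 h and that at 80 h, which share no library, had a Pearson r of -0.043 and a Spearman rho of -0.065; genes are not independent replicates. At least 2-fold higher at both times were 73 genes, where 93.8 would be if the calls at the 2 times were independent, and lower at both times 43 (43.6 if independent). Higher at 40 h and lower at 80 h were 112 genes (68.4 if independent), and lower at 40 h and higher at 80 h 69 (59.7). These counts depend on the scaling. In the same order they were 163 (200.8 if independent), 15 (16.6), 52 (27.4) and 119 (121.8) with total counts, 62 (76.4), 59 (57.05), 140 (89.4) and 58 (48.7) with the median of ratios, and 185 (214.95), 8 (9.82), 64 (34.2) and 74 (61.7) with the authors' FPKM. Of the 16 development genes, at 80 h 1 was higher, 0 lower and 15 not called, with a median of -0.25, but 0.29 with total counts and 0.27 without the 10 highest genes. SsgA-type SNA_RS05365 was 1.87-fold (1.45 to 2.43) higher and the chaplin SNA_RS11680 1.92-fold (1.76 to 2.09) lower at 80 h, neither of them called. A further SsgA-type gene, SNA_RS05675, was 1.49-fold (1.30 to 1.71) lower, not called.

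**Figure D4:**
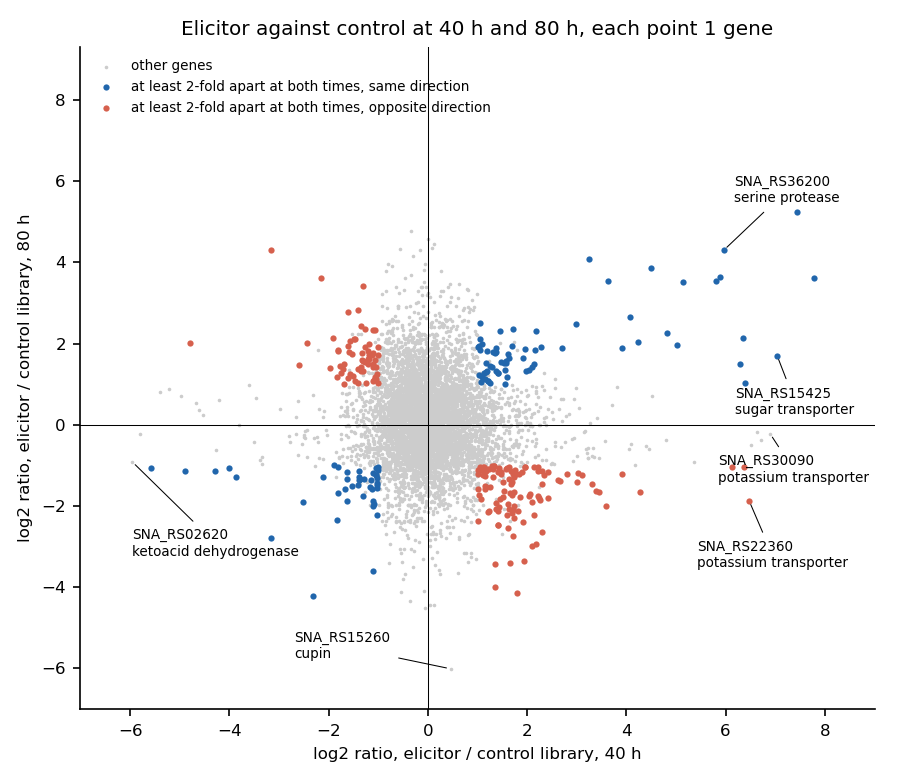
Log2 ratio of elicitor over control at 80 h against that at 40 h for the 6538 genes with counts in all 4 libraries, each point 1 gene and each ratio from 1 library per side. With TMM scaling, at least 2-fold apart at both times were 111 of these genes in the same direction and 173 in opposite directions.

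The time comparisons set the library of 80 h against that of 40 h. The files of the 2 harvests were processed differently, as whole counts and FPKM with 9 decimals at 40 h and as partly fractional counts and FPKM with 2 decimals at 80 h, so batch and time cannot be told apart. Without elicitor, the M4 peptidase SNA_RS32080 (contig 61, 305873 to 308152), of a family of secreted proteases, was 315-fold (296 to 335) higher, a branched-chain amino acid permease SNA_RS09650 (contig 10, 285480 to 287276) 229-fold (174 to 307) and the transporter-binding protein SNA_RS07010 172-fold (149.96 to 198). Phosphoenolpyruvate carboxykinase SNA_RS33855, which opens the route from organic acids back to sugars, was 138-fold (128 to 148) higher. The cupin SNA_RS15260 was 161-fold (139 to 187) higher, the inositol pathway dehydratase SNA_RS06085 139-fold (114 to 170.4), a methyltransferase SNA_RS24250 133-fold (87.1 to 214) and a hydrolase SNA_RS22140 125-fold (103 to 152).

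The 8 named genes ranked first by the ratio with the prior count among those lower at 80 h without elicitor all had 0 counts in that library, so their folds are bounds against a floor of 3 counts. Ribosomal protein L36 SNA_RS37435 was at least 873-fold lower, the glutamine amidotransferase SNA_RS25180 at least 228-fold, the ferredoxin SNA_RS27085 at least 94.6-fold, a methyltransferase SNA_RS09180 at least 86.4-fold and the membrane protein SNA_RS34995 at least 71.5-fold. Ribosomal protein L34 SNA_RS02340 was at least 71.2-fold lower, glycerate kinase SNA_RS27255 at least 62.5-fold and a cold-shock protein SNA_RS03665 at least 56.4-fold. Short genes were near 0 in both libraries of 80 h: of the genes of up to 200 bp, 59.4% in the control and 64.8% in the elicitor library had 0 counts, against 1.32% and 0.203% of the genes over 1500 bp. With genes at 0 counts set to their bound, the median log2 ratio of 80 h over 40 h of genes up to 200 bp was -1.52 without and -2.19 with elicitor, and that of genes over 1500 bp was 0.35 and 0.40.

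**Figure D5:**
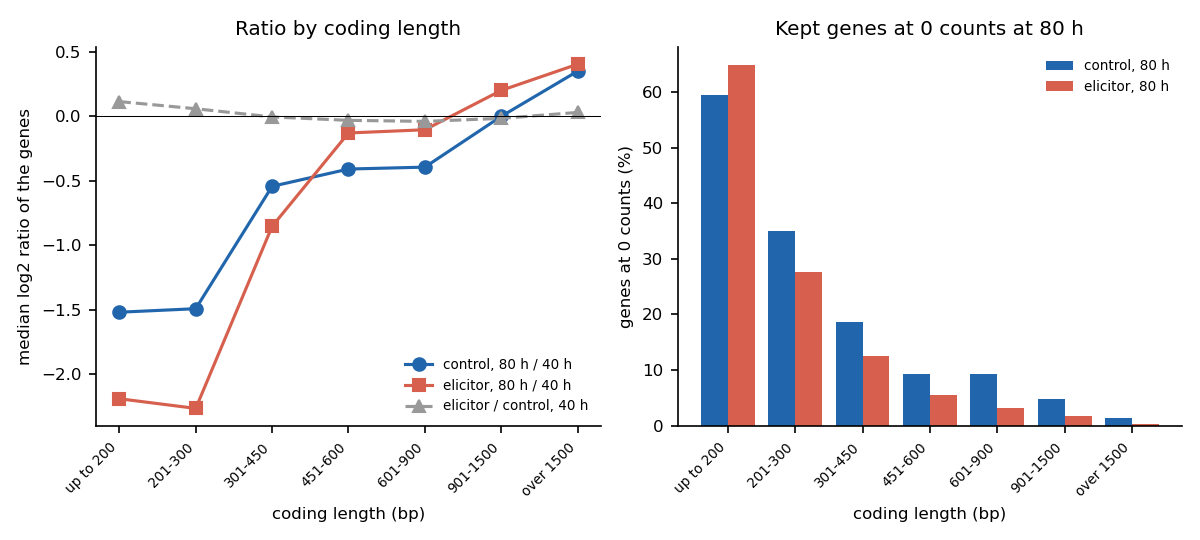
Median log2 ratio by coding length in bp for both time comparisons and the elicitor comparison at 40 h, with genes at 0 counts set to their bound, and the share of kept genes at 0 counts in the libraries of 80 h, 1 library per group. The share at 0 in the control library went from 59.4% of genes up to 200 bp to 1.32% of genes over 1500 bp.

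Without elicitor, 1997 genes were at least 2-fold higher and 2829 at least 2-fold lower at 80 h than at 40 h, 540 of the latter at 0 counts at 80 h. Scaled by total counts, the split was 1008 higher and 4188 lower, with the median of all genes moved by -1.06, and without the 10 highest genes it was 1023 and 4165 (a move of -1.04); the authors' FPKM gave 1088 and 3945. Of the 41 lists, 9 lay above and 10 below the middle 95% of random lists. Against shifts along the gene order 5 and 9 did, and respiratory chain, extender unit, osmoprotection, fatty acid degradation, glycolysis, TCA cycle and development lists lay inside, while the oxidative stress and cofactor lists lay below. Of those inside, the extender unit, glycolysis and development lists were so already for scattered lists after the median of each level bin was taken out. Terpene synthesis and development lay inside with total counts, development also with a prior count of 5, and ribosomal proteins, fatty acid degradation, development and general stress over genes of at least 600 bp. Of lists inside here, the cofactor list lay below with a prior count of 5, and over genes of at least 600 bp oxidative stress lay below and sigma factors above. Medians over genes of at least 600 bp, an alternative added after seeing the data, stand beside each list because of the short genes near 0.

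Energy, uptake and precursor lists had positive medians for 80 h over 40 h without elicitor. Respiratory chain genes (39, median 1.88, over long genes 1.76) had 26 higher, 5 lower and 8 not called. NADH-quinone oxidoreductase subunit I SNA_RS36925 was 42.4-fold (40.1 to 44.9) higher and the iron-sulfur subunit of succinate dehydrogenase or fumarate reductase SNA_RS33480 25.9-fold (23.9 to 28.1). Extender unit genes (median 1.93, long genes 1.75) had 8 higher, 2 lower and 4 not called. Methylmalonyl-CoA mutase SNA_RS32205 was 104-fold (89.7 to 121) higher and crotonyl-CoA reductase SNA_RS27220 17.996-fold (17.4 to 18.6). Osmoprotection genes (19, median 1.71, long genes 1.54) had 12 higher, 3 lower and 4 not called. Trehalose synthase SNA_RS32095 was 24.9-fold (23.9 to 25.8) higher and trehalose-phosphatase SNA_RS35725 40.2-fold (21.8 to 83.9) lower. Sugar transport and utilisation (median 1.62, long genes 1.46) had 22 higher, 6 lower and 8 not called. The permease SNA_RS32795 was 44.4-fold (33.9 to 59.2) higher and the phosphotransferase component SNA_RS05450 38.2-fold (19.3 to 88.6) lower. Peptide and amino acid transport had a median of 1.30 (long genes 1.03) with 22 higher, 6 lower and 13 not called.

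Cytochrome P450 genes (median 1.15, long genes 0.97) had 21 higher, 8 lower and 13 not called. SNA_RS19425 was 37.8-fold (33.8 to 42.5) higher and SNA_RS22945 42.7-fold (32.5 to 57.4) lower. Secreted hydrolases had a median of 0.94 (long genes 0.76), of -0.13 with total counts and -0.11 without the 10 highest genes, with 27 higher, 7 lower and 22 not called. The chitinase SNA_RS17910, which degrades chitin, was 76.9-fold (56.9 to 106) higher and the lipase SNA_RS29225 46.98-fold (32.5 to 70.3). Fatty acid degradation had a median of 0.36 (long genes 0.19), but -0.71 with total counts and -0.69 without the 10 highest genes, and 25 were higher, 19 lower and 22 not called. The long-chain fatty acid ligase SNA_RS36800 was 72.1-fold (60.8 to 86.03) higher, and enoyl-CoA hydratase SNA_RS35355, with 1 count at 80 h, 41.7-fold (7.39 to 1655) lower. Mobile elements (70 genes, median 0.44, long genes 0.93, but -0.63 with total counts and -0.61 without the 10 highest genes) had 26 higher, 13 lower and 31 not called. The transposases SNA_RS19375 and SNA_RS24020, at 121-fold (64.9 to 256) and 13.5-fold (9.40 to 19.9) higher, had fractional counts at 80 h, as repeated genes with shared reads do.

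Amino acid synthesis and sugar oxidation lists had negative medians for 80 h over 40 h without elicitor. Arginine synthesis (median -1.71, long genes -2.66) had 4 higher, 7 lower and 0 not called. The reductase SNA_RS12530 was 82.5-fold (37.8 to 225) lower and the acetyltransferase SNA_RS12535 23.5-fold (17.8 to 31.8). Aromatic and histidine synthesis (median -1.35, long genes -1.73) had 6 higher, 23 lower and 8 not called. Indole-3-glycerol-phosphate synthase SNA_RS13755 was 38.5-fold (14.97 to 142) lower and 3-dehydroquinate synthase SNA_RS15275 51.2-fold (44.9 to 58.6) higher. Sulfur and cysteine genes (24, median -1.09, long genes -1.42) had 2 higher, 12 lower and 10 not called. Methionine synthase SNA_RS31795, at 1 count, was 148-fold (26.5 to 5871) lower and cystathionine gamma-lyase SNA_RS02080, at 3 counts, 21.2-fold (7.20 to 104). Pentose phosphate genes (median -1.64, long genes -1.80) had 1 higher, 6 lower and 3 not called. The 6-phosphogluconolactonase SNA_RS10335, at 3 counts, was 272-fold (92.9 to 1318) lower and OpcA SNA_RS10340 13.6-fold (11.6 to 15.9). Glycolysis (median -0.71, long genes -1.01) had 4 higher, 7 lower and 7 not called. The 6-phosphofructokinase SNA_RS16550 was 6.56-fold (5.25 to 8.29) lower and phosphoglycerate mutase SNA_RS11635 6.16-fold (3.48 to 12.04). In the TCA cycle list (median -0.24, long genes -0.20) 8 were higher, 5 lower and 8 not called. The citrate synthase gene SNA_RS30285, at 1 count, was 132-fold (23.5 to 5204) lower.

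Terpene synthesis (10 genes, median -1.68, long genes -1.85) had 3 higher, 6 lower and 1 not called. Phytoene dehydrogenase SNA_RS09150, of carotenoid synthesis, was 47.3-fold (21.7 to 129) lower and the HpnD-type synthase SNA_RS25110, of hopanoid synthesis, 13.96-fold (8.42 to 25.1). The ribosomal protein list turned with gene length: its median was -0.99, at the bound -0.76, with 14 higher, 30 lower and 22 not called, and 0.57 over its 10 genes of at least 600 bp. General stress genes (27, median -1.64, at the bound -1.46, over 8 long genes -0.40) had 4 higher, 16 lower and 7 not called. The cold-shock protein SNA_RS26470, at 0 counts at 80 h, was at least 31.2-fold lower. Development genes (median -1.51, over 3 long genes -0.05) had 2 higher, 7 lower and 7 not called. The SsgA-family gene SNA_RS25450, at 1 count, was 81.5-fold (14.5 to 3229) lower. The WhiB-type regulator SNA_RS32765, of a family of iron-sulfur regulators of development, was 51.6-fold (40.9 to 66.1) lower.

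With elicitor, named genes that were higher at 80 h than at 40 h included a transporter, metal resistance genes and a regulator, and those lower included several small proteins. The branched-chain amino acid permease SNA_RS09650 was 169-fold (138 to 209.9) higher at 80 h, the TerC-type tellurium resistance protein SNA_RS09830 99.7-fold (76.8 to 132), a copper oxidase SNA_RS20600 69.02-fold (52.2 to 92.96), a phosphotransferase family protein SNA_RS17890 47.6-fold (36.6 to 62.8), the PaaX-type regulator SNA_RS29725 46.6-fold (32.9 to 67.9) and a radical SAM protein SNA_RS28670 32.4-fold (27.1 to 38.9). The transposases SNA_RS19375 and SNA_RS18415, with fractional counts, were 151-fold (90.8 to 272) and 47.1-fold (25.99 to 93.6) higher. Ribosomal proteins L36 SNA_RS37435 and L34 SNA_RS02340, both at 0 counts at 80 h, were at least 1061-fold and at least 177-fold lower, and subunit F of the potassium ATPase SNA_RS38935, a gene of 90 bp, at least 663-fold lower. Also at 0 were a cold-shock protein SNA_RS26470 (at least 61.3-fold lower), TatA SNA_RS00475 of the twin-arginine export system (at least 48.7-fold), an anion permease SNA_RS04715 (at least 37.7-fold) and a DNA hydrolase SNA_RS28240 (at least 26.9-fold); the biotin transporter BioY SNA_RS08570, at 3 counts, was 414-fold (142 to 2009) lower.

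With elicitor, 1734 genes were at least 2-fold higher and 2506 at least 2-fold lower at 80 h, 350 of the latter at 0 counts. Total counts gave 972 and 3255 with the median of all genes moved by -0.54, total counts without the 10 highest genes 974 and 3253 with the same move, and the authors' FPKM 926 and 3177. Of the 41 lists, 6 lay above and 5 below the middle 95% of random lists. Against shifts along the gene order 4 and 6 did, and the polyene cluster, translation factor, respiratory chain and sulfur lists lay inside, while the arginine, general stress and iron transport lists lay below. The translation factor and respiratory chain lists were inside already for scattered lists after the level-bin step. Development and secreted hydrolases lay inside over genes of at least 600 bp. Of lists inside here, glycolysis, pentose phosphate, arginine and oxidative stress lay below with that length, arginine also with a prior count of 5, and fatty acid degradation and TetR-type regulators above with a filter of 100 counts. Across genes the time ratios with and without elicitor, which share no library, had a Pearson r of 0.80 and a Spearman rho of 0.83. Both ratios share the different processing of the 2 harvests and the low counts of short genes at 80 h. Their correlation therefore does not set time apart from batch.

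Translation factors (median 1.36, long genes 1.15) had 21 higher, 2 lower and 13 not called at 80 h with elicitor: elongation factor G SNA_RS12790 was 9.73-fold (8.90 to 10.6) higher, while initiation factor IF-1 SNA_RS37430, a short gene, was 47.1-fold (38.2 to 58.7) lower. Respiratory chain genes (median 1.22, long genes 1.16) had 22 higher, 3 lower and 14 not called. Cytochrome c oxidase subunit II SNA_RS08910 was 6.66-fold (6.57 to 6.75) higher and NADH-quinone oxidoreductase subunit I SNA_RS36925 6.28-fold (6.03 to 6.54). Sugar transport and utilisation (median 1.07, long genes 0.84) had 20 higher, 8 lower and 8 not called. Named by a ratio that rests on the prior count, the binding protein SNA_RS36270 and xylose isomerase SNA_RS06005 were at least 8.21-fold and at least 7.85-fold lower, each at 0 counts at 80 h. Peptide and amino acid transport (median 0.89, long genes 0.62) had 19 higher, 6 lower and 16 not called, the permease SNA_RS07140 being 17.7-fold (13.8 to 22.9) lower. Secreted hydrolases (median 0.65, long genes 0.38) had 23 higher, 6 lower and 27 not called. The chitinase SNA_RS17910 was 17.2-fold (13.6 to 22.01) higher and the lipase SNA_RS03380, at 2 counts, 13.8-fold (3.75 to 115) lower. Mobile elements had a median of 0.32 (long genes 0.63), but of -0.20 both with total counts and without the 10 highest genes, with 22 higher, 13 lower and 35 not called.

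The development list had a median of -2.34 at 80 h with elicitor, with 0 higher, 9 lower and 7 not called of 16, but of -0.16 over its 3 long genes. The WhiB-type regulator SNA_RS32765 was 124-fold (101 to 155) lower and the chaplin SNA_RS10925 47.5-fold (32.4 to 72.8), both short genes. Ribosomal protein genes had a median of -1.60, at the bound -1.38 and over 10 long genes -0.17, with 10 higher, 38 lower and 18 not called. Sulfur and cysteine genes (median -0.80, long genes -1.09) had 2 higher, 10 lower and 12 not called. Cystathionine gamma-synthase SNA_RS03685 was 6.61-fold (5.75 to 7.63) lower and a cysteine synthase SNA_RS15150 5.88-fold (5.19 to 6.67) higher. Aromatic and histidine synthesis (median -0.67, long genes -0.94) had 5 higher, 17 lower and 15 not called. Tryptophan synthase alpha SNA_RS09495 was 8.19-fold (5.37 to 13.1) lower and anthranilate phosphoribosyltransferase SNA_RS13760 7.51-fold (5.13 to 11.5). The polyene cluster list had a median of -0.29 (long genes -0.50) with 7 higher, 12 lower and 22 not called with elicitor. This lay below the middle 95% of random lists but inside when set against shifts along the gene order. Without elicitor the list's median was 0.35 (long genes 0.08) with 10 higher, 12 lower and 19 not called, inside the middle 95% of random lists. That median was -0.73 with total counts and -0.71 without the 10 highest genes. Within the polyene cluster list, with elicitor, the LuxR-type regulator SNA_RS21305 had a log2 ratio of 80 h over 40 h of -1.40 (-1.43 to -1.36), the regulator SNA_RS21310 3.35 (3.26 to 3.45), the aminotransferase SNA_RS21360 1.62 (1.60 to 1.64) and the P450 SNA_RS21390 -1.96 (-2.04 to -1.88).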

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

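All tests in this part were chosen only after the result was seen, except the correlation over means of adjacent genes, which was fixed before its value was seen.

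Among the named genes 14 were at least 2-fold apart in opposite directions at 40 h and 80 h, which is what marks them here; with 1 library per group the difference between the times was not tested. The values are the log2 ratio of elicitor over control at 80 h minus that at 40 h. Genes higher at 40 h and lower at 80 h included transporters. SNA_RS22360, listed as potassium transporter KtrB, had -8.34 and subunit C of the potassium ATPase SNA_RS30085 -7.42. The branched-chain amino acid binding protein SNA_RS09660 had -3.96 and the amino acid permease SNA_RS11095 -2.76. On contig 25 the genes of this direction were 3-dehydroquinate synthase SNA_RS15275 with -5.93, the cupin SNA_RS15300 with -5.34 and fructose-bisphosphate aldolase SNA_RS15280 with -5.12. Enzymes elsewhere were xylose isomerase SNA_RS20580 with -4.15, the Clp protease subunit SNA_RS16770 with -3.77, the iron-sulfur subunit of succinate dehydrogenase or fumarate reductase SNA_RS33480 with -3.26, phospholipase C SNA_RS36720 with -3.25 and the glycosyl hydrolase SNA_RS14050 with -2.99. Genes lower at 40 h and higher at 80 h were the Ohr peroxiredoxin SNA_RS17690 with 3.37 and the glutamine amidotransferase SNA_RS25180 with at least 6.84, whose control library of 80 h had 0 counts. The list of TetR-type regulators lay below random lists at 40 h (median -0.19) and above them at 80 h (0.56), a difference of 0.75. With total counts, and also without the 10 highest genes, 3 of the 14 were under 2-fold apart at 80 h: with total counts SNA_RS14050 had a log2 ratio of -0.67, SNA_RS30085 -0.51 and SNA_RS36720 -0.50. In all genes 181 calls were opposite at the 2 times, and 171 with total counts.

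Across genes the elicitor ratios at 40 h and 80 h had an r of -0.043. Counting error in the thinner libraries of 80 h is argued against by the 694 genes of at least 600 bp with at least 1000 counts in every library, over which r was -0.047 (95% of resamples of genes -0.15 to 0.05; -0.036 and -0.070 with minimums of 100 and 3000 counts), where 0.3 or more would mark that cause, a limit chosen after this r was seen. Uneven recovery of single genes at 80 h is argued against as the whole cause by means over 293 pairs of adjacent genes, whose r was -0.114 (-0.23 to -0.02) against the same limit, and -0.033 and -0.020 with minimums of 30 and 300 counts in place of 100. Whether recovery was uneven in part stays open, since the lower r between partners of a pair at 80 h (0.606, against 0.921 at 40 h) can come from batch or from time. Different processing of the 2 harvests and a difference between cultures that a second culture would not repeat could not be tested with 1 library per group, and a response to the elicitor that differs between the times also stays open, untested.

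Short genes were at or near 0 counts in both libraries of 80 h. Lower depth is argued against: the 40 h libraries thinned to the depth of those of 80 h had at most 57 kept genes at 0 in 100 draws each, against 782 in the control and 477 in the elicitor library of 80 h. These counts are of genes of all lengths. Of genes over 200 and up to 300 bp, 180 and 142 were at 0 at 80 h in the control and elicitor library. Of genes over 600 and up to 900 bp, 168 and 58 were at 0. Loss of short genes in recovery or counting at 80 h may account for the short genes near 0, but not for the longer genes at 0. Ribosomal protein genes under 300 bp (25 genes) had a median time ratio lower than the 41 longer ones by a difference of -2.86 without and -3.43 with elicitor. That the short ribosomal proteins were set apart from the long ones by culture time stays open, since batch and time cannot be told apart here.

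The potassium transport genes were far higher in the elicitor library at 40 h and not at 80 h. Over 4 scalings the lowest of the log2 ratios of 5 genes (SNA_RS30085, SNA_RS30090, SNA_RS30095, the subunit F gene SNA_RS38935 and SNA_RS22360) was 5.99, but these scalings moved the median of all genes at 40 h by no more than 0.0124 and so do not test scaling as a cause. A scaling factor shifts all genes by 1 amount, apart from those near 0 counts, and the median of all genes was -0.01. This argues against scaling as the source of the gap between these 5 genes and the median gene. Reads shared between near-identical genes are argued against for the 4 genes with counts at 80 h, of which 0 had a fractional expected count there, where 54 genes had one. For SNA_RS38935, with 0 counts in both libraries of 80 h, shared reads stay open. The other 4 genes were not near 0 at 80 h. In the control SNA_RS30085, SNA_RS30090, SNA_RS30095 and SNA_RS22360 had 173, 382, 539 and 73 counts at 40 h. In the smaller control library of 80 h they had 962, 1347, 2569 and 374. The elicitor library of 80 h had 709, 1767, 2756 and 156. The control level was thus higher at 80 h for these 4, and batch and time cannot be told apart. A difference in potassium supply between the 2 cultures, or a chance difference of single cultures, stays open beside a response to the elicitor, and none of these was tested.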

How the results depend on the processing

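The alternatives with genes of at least 600 bp, TMM within 1 harvest time, letter case kept, the narrower cluster span, shifts along the gene order, the calls at both times under each scaling and the additive fit were chosen after seeing the data; all others were planned. Of 84 gene counts under alternatives 57 stayed within 1.5 times the main count. Of 385 list medians 225 stayed within their counting range, 146 left it, and 14 medians of lists outside the range of random lists turned sign. Medians of lists inside that range are counted by their distance only. Of 1188 values of named genes and genes of the narrower cluster span, 919 stayed within their interval and 269 left it. The direction of a called gene turned in 0 of them, but 6 cluster genes that were not called turned sign at 80 h with total counts, the same 6 without the top 10 genes and 2 others with the median of ratios. Scaling by total counts moved the log2 ratios of named genes by -1.08 to 0.55, by total counts without the top 10 genes by -1.06 to 0.54, by the median of ratios by -0.14 to 0.10; the filter of 100 counts by -0.06 to 0.01 and a prior count of 5 by -0.74 to 3.33, the largest moves being for genes at or near 0 counts.

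Scaling by total counts gave 1996 higher and 272 lower genes with elicitor at 80 h, 1008 higher at 80 h without elicitor and 972 with elicitor. Total counts without the top 10 genes gave 1964 and 277, 1023 and 974. With the authors' FPKM, which are scaled by a library total, 249 genes were lower with elicitor at 40 h, 1839 higher and 293 lower at 80 h, and 1088 and 926 higher at 80 h without and with elicitor. Total counts turned the medians of fatty acid degradation (0.01 with elicitor at 80 h, -0.71 over time without elicitor), peptide and amino acid transport (0.01), cytochrome P450 (0.09), secreted hydrolases over time without elicitor (-0.13) and mobile elements over time (-0.63 without and -0.20 with elicitor). Without the top 10 genes the turned medians were -0.69 for fatty acid degradation and -0.11 for secreted hydrolases over time, 0.07 for cytochrome P450 and -0.61 and -0.20 for mobile elements. Both scalings by total counts shift the ratios of a comparison by 1 amount, apart from genes at or near 0 counts, and by construction this shift is the cause; for FPKM the cause was not tested.

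A threshold of 1.5-fold gave 1437 higher and 1242 lower genes with elicitor at 40 h and 1452 and 1306 at 80 h. A threshold of 4-fold gave 177 and 70 at 40 h, 283 and 156 at 80 h, 1074 higher over time without elicitor, and 548 higher and 1666 lower with elicitor. With genes of at least 600 bp, where fewer genes are counted, 303 genes were lower with elicitor at 40 h, and 1100 were higher and 1649 lower over time with elicitor. In that setting 8 lists lay below random lists over time with elicitor (5 in the main setting), the ribosomal protein median over time without elicitor was 0.57 (10 genes) and the development median at 40 h was -0.10 (3 genes); the cause was not tested. With shifts along the gene order in place of scattered random lists, 2 lists lay above with elicitor at 40 h (5 in the main setting) and 5 over time without elicitor (9 in the main setting). That setting also takes out the median of each level bin. With that done and lists still scattered, the 3 lists at 40 h stayed outside, so keeping neighbours together made the difference there; over time the extender unit list was inside already (percentile 95.33). Spearman rho of the elicitor ratios at 40 h and 80 h was -0.075 with the filter of 100 counts, and the cause was not tested.

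The smaller pseudocount planned for normalized values gave no value, since the main unit is counts. No gene was described as a stable RNA, though 303 genes have no description, so that setting left out only the top 10 genes, and there was no replicate to leave out. No paired analysis was possible because the groups share only 1 replicate number. With harvest time as a block, the additive fit (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05) called 2 of 7426 genes as higher with elicitor, the hypothetical protein SNA_RS22215 and the serine protease SNA_RS36200, and 0 as lower. At an unadjusted p under 0.05 it was 120 higher and 72 lower. SNA_RS22215 was chosen for mention after its values were seen. Depth limits the 80 h comparison most, where 834 genes differed 2-fold with an interval that held 1.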

Other observations

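All tests and choices in this part were made only after the result was seen. Some genes apart with elicitor lay side by side, more of them at 40 h than at 80 h, and how many runs chance would give was not computed. At 40 h there were 18 runs of at least 5 neighbouring higher genes (132 genes) and 7 runs of lower ones (50 genes), and at 80 h 1 run of higher genes (5 genes) and 5 of lower ones (43 genes). On contig 45, 11 genes from 204370 to 241383 with non-ribosomal peptide synthetases, which build peptides without a ribosome, had a median log2 ratio of 2.55 at 40 h and -0.82 at 80 h. Beside them 12 genes from 184959 to 201124, with an amidinotransferase and cytochrome P450 genes, had 3.21 and -0.68. On contig 12, 17 genes from 63048 to 78933 with a peptide synthetase had 1.69. The lower run with the lowest median, 10 genes from 777419 to 786977 on contig 29 with an RNA polymerase sigma factor, a cytochrome P450, PvcA and an ABC transporter, had -4.73 at 40 h, and 6 genes on contig 3 from 346653 to 351572, an acyl-CoA dehydrogenase and 5 phenylacetate degradation genes, had -4.14. On contig 18, 9 genes from 283213 to 293875 with anthranilate synthase and enzymes of 2,3-diaminopropionate synthesis had -1.47 at 40 h, and 5 of them were higher at 80 h. On contig 61, 5 genes from 308461 to 318657, for a peptidase, a maltosyltransferase, trehalose synthase, maltokinase and glycogen branching, had 1.59 at 40 h.

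At 80 h the longest run was 15 lower genes on contig 25 from 26577 to 46058 with a median of -2.99, 9 of them higher at 40 h. Of 10 genes on contig 29 from 145767 to 157056 with xylose isomerase and a partial glucoamylase, all higher at 40 h (median 1.70), 9 were lower at 80 h. A run of 8 genes on contig 8 from 275028 to 285133, with inositol breakdown enzymes, an MFS transporter and a hypothetical protein, had -2.28 at 80 h, and 5 genes on contig 34 from 717296 to 724174 with carbon monoxide dehydrogenases had -2.52.

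Whether strong ratios at 40 h went with the same or the opposite direction at 80 h depended on the threshold, with TMM scaling. Of the 729 genes at least 2-fold higher with elicitor at 40 h, 73 were higher and 112 lower at 80 h (93.8 and 68.4 if independent). Of 177 at least 4-fold higher, 29 were higher and 33 lower (22.8 and 16.6), and of 65 at least 8-fold higher, 19 and 12 (8.37 and 6.10). Of the 34 genes at least 16-fold higher with elicitor at 40 h, 15 were at least 2-fold higher at 80 h, where 4.38 would be if the calls were independent, and 4 were lower (3.19 if independent). Of the 18 genes at least 16-fold lower, 3 were higher and 4 lower (2.32 and 1.69). Neighbouring genes among them are not independent of each other. At least 4-fold higher at both times, with at least 100 counts in a library of each time, were 12 genes, and 1 was lower. The hypothetical proteins SNA_RS22210 and SNA_RS22215 had log2 ratios of 7.78 (7.61 to 7.96) and 7.45 (7.20 to 7.73) at 40 h and 3.62 (3.48 to 3.77) and 5.25 (3.92 to 7.18) at 80 h, and the cyclase SNA_RS22220 beside them 5.14 (4.80 to 5.54) and 3.52 (2.67 to 4.56). The serine protease SNA_RS36200 had 5.96 (5.79 to 6.15) and 4.30 (4.16 to 4.44), and the kinase SNA_RS36190 and regulator SNA_RS36195 beside it 4.49 (4.27 to 4.73) and 5.80 (5.52 to 6.11) at 40 h. The penicillin-binding protein SNA_RS06560 had 2.99 (2.75 to 3.24) and 2.47 (2.20 to 2.76), and the MarR-type regulator SNA_RS27400 2.18 (1.78 to 2.64) and 2.30 (1.59 to 3.10). The lower gene was SNA_RS05345, 4-hydroxyphenylpyruvate dioxygenase of tyrosine breakdown, with -3.16 (-3.22 to -3.09) and -2.78 (-2.94 to -2.63).

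Adjacent genes shared less of their elicitor ratio at 80 h than at 40 h. Over 293 pairs of adjacent genes with at least 100 counts in every library the r of the partners' ratios was 0.92 at 40 h (95% of resamples 0.86 to 0.96) and 0.61 at 80 h (0.52 to 0.69). With minimums of 30 and 300 counts, also tried, it was 0.869 and 0.939 at 40 h and 0.569 and 0.591 at 80 h. Lower depth at 80 h is unlikely to account for this, since the 40 h libraries thinned to the depth of 80 h kept an r of at least 0.897 in 100 draws. The level per length of adjacent genes differed by a median log2 of 0.658 and 0.619 in the control and elicitor libraries of 40 h and 1.40 and 1.03 in those of 80 h. Batch and time cannot be told apart here.

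A further hypothesis is that the elicitor culture was ahead along the time course at 40 h. Across genes the elicitor ratio at 40 h had an r of 0.070 (0.05 to 0.09) with the mean of the time ratios, and of 0.227 with the time ratio without and -0.132 with that with elicitor. Each time ratio shares a 40 h library with the elicitor ratio, the control with like and the elicitor library with opposite sign, and no value without that sharing can be had from 4 libraries. The hypothesis therefore stays open.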
